A study of Homo sapiens with 28 samples.

How the data were processed

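RNA was measured in SK-N-MC cells, an established line, that carried 1 of 4 doxycycline-inducible short hairpin RNAs. Cultures received 100 ng/ml doxycycline for 24 or 48 h. Per the labels' protocols, RNA was extracted with a column kit that included DNase digestion, libraries were made with a stranded total RNA kit, and paired ends were read on a HiSeq2000. The labels call the samples biological replicates. At each time there were 5 shScramble, 3 shFLI1, 3 shCHD4#1 and 3 shCHD4#2 libraries. Groups were taken from the titles and the treatment labels. The genotype label of the 48 h shScramble samples reads CHD4 knockdown, against their titles and treatment labels, and CHD4 reads in those libraries had the level of the 24 h shScramble libraries.

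Per the submitters' processing notes, the tools behind the deposited files were FastQC 0.11.7, HISAT2 2.1.0, SAMtools 1.7, featureCounts 1.6.0 and DESeq2 1.34.0 with the GRCh38 build. Their parameters, the annotation release and the strand setting of read counting are not given in the sources used here. The authors deposited a signal per gene and library, gene read counts divided by 1 size factor per library, in a table for each time. Both tables hold the same 28 libraries and 35488 genes, with a largest relative difference of 4.98e-07, so libraries of both times share 1 scale. The smallest sum of reads over all libraries was 10, which is where low genes had been removed before deposit. The authors' comparison tables give a log2 fold change with its error, a p-value and an adjusted p-value per gene, and in 1 table a score, the test statistic. In the 5 that hold the comparison in their name the unadjusted p is exactly 1 for 36.9 to 68.8 percent of genes (0.0197 percent in the other), as when fold changes are tested against a minimum, which is not stated. The deposited table named for shFLI1 at 24 h holds another comparison, shScramble at 48 h against 24 h, and was not used for shFLI1.

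Each library's values were whole multiples of the value of 1 read, for 100 percent of values within a tolerance of 0.02, so whole reads could be recovered. Recovered reads ranged from 46102707 to 64775441 per library. Mitochondrial ribosomal RNA took 15.2 to 22.5 percent of reads and the 10 most abundant genes took 20.6 to 30.5 percent. Where a named fold change rests on 3 or fewer reads in a group, the ratio of reads is given with an exact 95% binomial interval, which covers counting error only. None of the 38 pairs of libraries within a group was alike within sampling noise (chi-square per gene 8.72 to 149).

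The following choices were fixed before the data were examined: groups, tests, gene lists, the rule for named genes and most alternatives. Because the deposited values are normalised, the main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2 of the value plus a pseudocount of 1. Fold changes are therefore on that scale, which understates the change of low genes. Genes with a mean of at least 10 over all 28 libraries were tested, 21025 of 35488. Each time was fitted alone with its 4 groups, which shared 1 estimate of the spread. P values were adjusted by the Benjamini-Hochberg method within a comparison and called at 0.05. Each knockdown was compared with shScramble, the CHD4 hairpins with each other, shFLI1 with the mean of both hairpins, and the fold changes at 48 h with those at 24 h. All tests were two-sided, and values with ± are the mean and SD over 5 shScramble or 3 knockdown libraries.

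Genes were named by a fixed rule. The targets CHD4, FLI1 and EWSR1 are always given. For shFLI1 at each time, the 8 largest rises and the 8 largest falls were taken among genes that passed the test, whose 3 knockdown values all lay outside the range of the 5 shScramble values and whose mean was at least 100 in the higher group. For CHD4 the same conditions had to hold with both hairpins in 1 direction, and genes were ranked by the smaller of the absolute changes. Genes known only by a clone or identifier were passed over, as were any that could tell the sex of a donor. Up to 4 members of each list with the smallest adjusted p were added. Any other gene is said to have been chosen after its values were seen. Positions are those of whole genes in GENCODE release 29 on GRCh38, in which 34232 of the genes were found. Antisense transcripts, pseudogenes and near-identical copies are uncertain, since the strand setting and the treatment of shared reads are not given.

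Gene lists were written from textbook knowledge. They covered EWS-FLI1 activated targets (42 of 43 genes tested), EWS-FLI1 repressed targets (29 of 33), NuRD complex subunits (15 of 15), neuronal genes (24 of 30), striated muscle genes (15 of 30), mesenchymal and extracellular matrix genes (30 of 32), p53 target genes (24 of 25), DNA repair genes (30 of 30), DNA replication and E2F target genes (32 of 32), mitosis genes (32 of 32), interferon response and antigen presentation genes (20 of 29), ATF4 and unfolded protein response genes (26 of 26), cholesterol synthesis genes (24 of 24), glycolysis and hypoxia genes (26 of 27), immediate early and AP-1 genes (22 of 25), germline genes (12 of 32), HOX genes (33 of 39) and apoptosis regulators (27 of 30). Markers of other cell types were epithelial genes (10 of 20) and haematopoietic and endothelial genes (8 of 23). Mitochondrially encoded genes (15 of 15), replication-dependent histone genes (30 of 32) and cytosolic ribosomal protein genes (40 of 40) served as signs of RNA quality. Lists were tested against all other genes with camera at its preset correlation, adjusted over the 23 lists of a comparison. Camera with the correlation estimated per list, and fry, were alternatives. Of all calls against shScramble, only that of the EWS-FLI1 repressed targets in shFLI1 at 48 h held with an estimated correlation.

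The libraries fell into 2 kinds by the level of processed pseudogenes, gene copies that share sequence with their parent. A score, the median log2 value of 164 such pseudogenes minus that of 11998 protein-coding genes after centring each gene on its mean, was 0.305 to 0.487 in 12 libraries and -0.695 to 0.00484 in 16. The first kind held replicates 1 and 2 of shScramble and of both CHD4 hairpins at each time, and the second kind all others, including all 6 shFLI1 libraries. No label gives the kind. Whether equal replicate numbers pair the libraries was checked from the correlation of their deviations from the group means. It was 0.292 to 0.596 for shCHD4#1 and 0.339 to 0.615 for shCHD4#2 against shScramble at 24 h, 0.220 to 0.509 and 0.129 to 0.485 at 48 h, and 0.311 to 0.708 and 0.240 to 0.594 between the hairpins. The numbers were taken to pair these libraries, which share a kind, not those of shFLI1. The main test ignored pairs.

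Alternatives were pseudocounts of 0.5 and 5, no filter, a filter at a mean of 50, median centring, quantile normalisation, a fit of only the groups compared, a replicate block, robust variance estimates, a fold minimum, each library left out in turn, edgeR 4.0.16 (quasi-likelihood with TMM factors) and DESeq2 1.42.0 on the recovered reads, and the authors' tables. Library kind as a term, the second kind only and the first kind only were added after seeing the data. Comparisons that share the shScramble libraries were set beside 50 simulated draws of unchanged groups and beside 20 assignments in which the controls were split into 2 and 3. Each test was first run on 21025 simulated genes in 6 comparisons, with 66 or 67 changed by each known amount. Limma-trend recovered 5.97 to 31.3 percent of changes of log2 0.5, 52.2 to 74.6 percent of changes of 1 and 74.2 to 93.9 percent of changes of 2, and 2.42 to 9.3 percent of its calls were false. For edgeR the false share was 4.5 to 10.3 percent. For DESeq2 it was 14.6 to 22.7 percent, above the 5 percent aimed at, so its counts serve only as a side value. The test of a difference between fold changes recovered 47.8 to 55.3 percent of differences of 1, with 6.8 to 9.13 percent of its calls false. Camera found a changed list of 30 genes, drawn independently, in 6 of 6 comparisons and called 0 of 22 unchanged lists in each.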

Results

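SK-N-MC is a line of Ewing sarcoma, a tumour of bone and soft tissue in which a fusion of EWSR1 with FLI1 encodes the transcription factor EWS-FLI1. CHD4 is an ATPase subunit of the nucleosome remodelling and deacetylase (NuRD) complex. The series asks how expression changed 24 and 48 h after EWS-FLI1 or CHD4 was silenced by an inducible hairpin. Total RNA from 28 libraries gave 46102707 to 64775441 recovered reads each. Each time had 5 shScramble control, 3 shFLI1, 3 shCHD4#1 and 3 shCHD4#2 libraries. Values below are normalised counts as mean ± SD over those libraries and log2 fold changes with limma's standard error and adjusted p. Libraries of the first kind, replicates 1 and 2 of shScramble and of both CHD4 hairpins, held more reads of processed pseudogenes than the others.

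**Figure D1:**
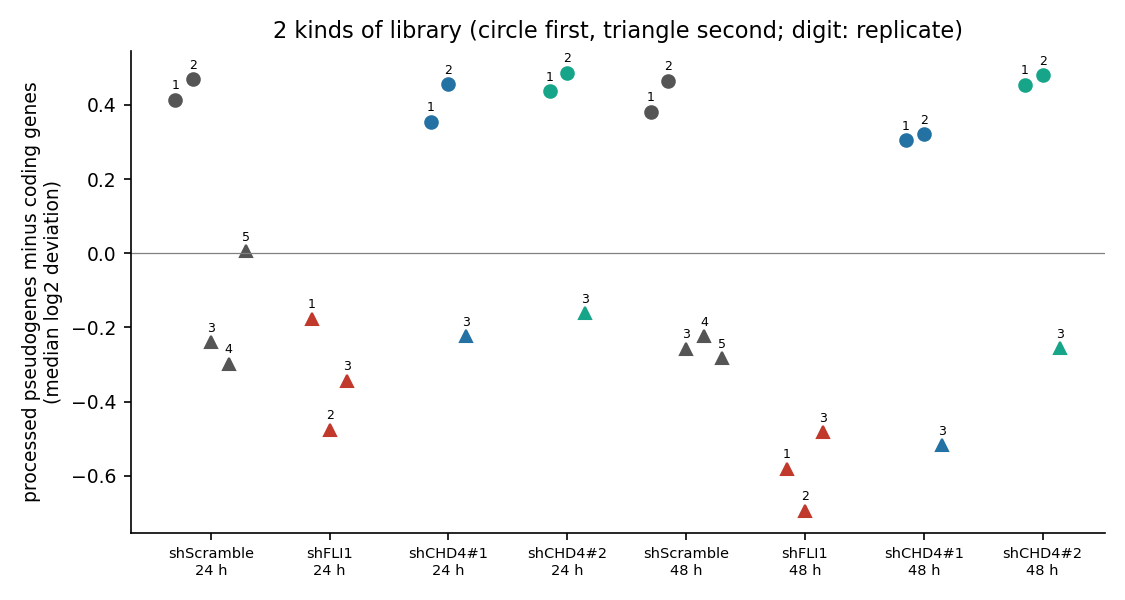
Each point is 1 of the 28 libraries, with the median log2 value of processed pseudogenes minus that of protein-coding genes on the vertical axis. The 12 libraries of the first kind lie between 0.305 and 0.487 and the 16 of the second kind between -0.695 and 0.00484.

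CHD4 fell with both of its hairpins, at both times and in all 3 libraries of each. At 24 h shScramble libraries held 11550.1 ± 1236 CHD4 counts, against 2989.9 ± 239.5 with shCHD4#1 (log2 -1.95, SE 0.11, limma adjusted p = 4.74e-07) and 3075 ± 351 with shCHD4#2 (log2 -1.91, adjusted p = 5.76e-07). At 48 h the level was 11605 ± 1563 in shScramble, 3189 ± 267 with shCHD4#1 (log2 -1.86, adjusted p = 9.38e-08) and 2749.9 ± 44.1 with shCHD4#2 (log2 -2.07, adjusted p = 2.57e-08). CHD4 (ENSG00000111642) lies on chromosome 12, 6570082 to 6614524, on the minus strand of GRCh38. FLI1 (ENSG00000151702, chromosome 11, 128686535 to 128813267, plus strand) fell with shFLI1 from 4153 ± 408 to 1856 ± 148 at 24 h (log2 -1.16, adjusted p = 3.58e-07) and from 3783 ± 454 to 1669 ± 141 at 48 h (log2 -1.17, adjusted p = 6.15e-07). Reads of FLI1 include those from the part of FLI1 that the fusion retains, and the values do not part the fusion from FLI1 itself. EWSR1 (ENSG00000182944, chromosome 22, 29268009 to 29300525, plus strand), the other partner, was at log2 -0.07 with shFLI1 at 24 h (adjusted p = 0.568), a sign that turned with quantile normalisation and with a replicate block. At 48 h it fell by log2 0.35 (adjusted p = 0.00768), a call that ended with quantile normalisation (log2 -0.09, adjusted p = 0.299).

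CHD4 was higher with shFLI1 at 24 h, at 14570.0 ± 1248 (log2 0.34, adjusted p = 0.0176), and at log2 0.18 at 48 h (adjusted p = 0.139). The 24 h call ended without shFLI1 replicate 3 (CHD4 at log2 0.27, adjusted p = 0.0952), with median centring (0.0576) and against second-kind controls alone (0.058). FLI1 did not pass the test with shCHD4#1 at 24 h (log2 -0.16, adjusted p = 0.345) or 48 h (-0.12, 0.47), nor with shCHD4#2 at 24 h (-0.15, 0.389). With shCHD4#2 at 48 h FLI1 was at 2974 ± 355, log2 -0.34 (adjusted p = 0.0291). That FLI1 call ended without replicate 3, 4 or 5 of shScramble (adjusted p = 0.0549, 0.0654 and 0.058) or replicate 2 or 3 of shCHD4#2 (0.159 and 0.0771), and with a replicate block (log2 -0.25, adjusted p = 0.117). EWSR1 was lower with shCHD4#2 at 48 h (log2 -0.39, adjusted p = 0.00873), but not without its replicate 2 (adjusted p = 0.0607).

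**Figure D2:**
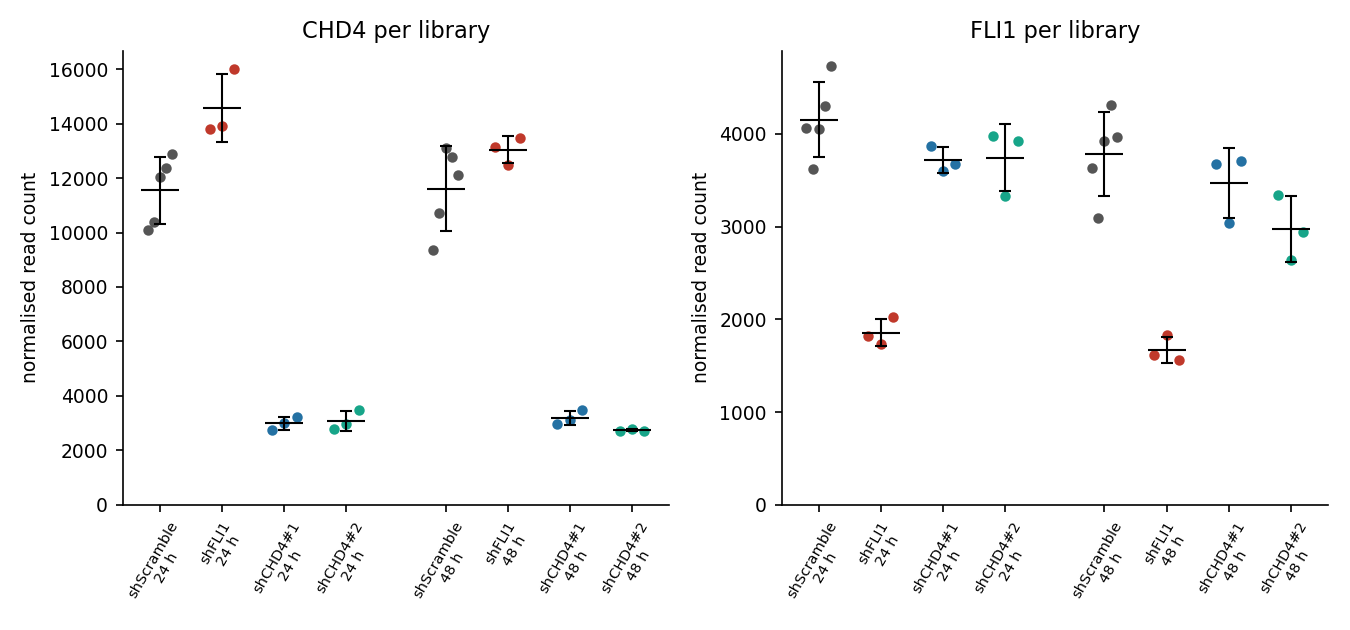
Normalised counts of CHD4 and FLI1 in each library, with the mean ± SD of each group at 24 and 48 h. CHD4 was 11605 in shScramble and 2749.9 with shCHD4#2 at 48 h, and FLI1 was 3783 in shScramble and 1669 with shFLI1.

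At 24 h of shFLI1, 33 of 42 EWS-FLI1 activated targets were lower and 4 higher, and 18 of 29 repressed targets were higher and 3 lower (adjusted p = 7.44e-13 and 9.36e-05, and adjusted p = 0.0929 for each list with an estimated correlation). CCND1, which encodes cyclin D1 of the G1 phase, fell from 10914 ± 2911 to 427 ± 128 (log2 -4.67, SE 0.22, adjusted p = 2.15e-09). MYC, a growth-promoting transcription factor, fell from 17309 ± 1182 to 1940.0 ± 587 (log2 -3.19, adjusted p = 1.54e-09). CDKN1C, an inhibitor of cyclin-dependent kinases, rose from 204 ± 36 to 3202 ± 325 (log2 3.98, adjusted p = 1.94e-09). Of 21025 genes, 5083 were higher and 4727 lower, with 2266 and 1603 at least 2-fold.

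The largest rise under the naming rule was COL9A1, a collagen of cartilage (chromosome 6, 70215061 to 70303083), from 4.69 ± 2.01 to 984 ± 258 (log2 7.46, adjusted p = 4.22e-09). The cell adhesion cadherin CDH10 followed at log2 6.99, then LINC02044 (6.58), the sulfatase ARSJ (6.57), the Wnt inhibitor DKK1 (6.48), SHROOM4 (6.42), PRR32 (6.41) and SIPA1L2 (6.30). DKK1 (chromosome 10, 52314296 to 52318042) had 304 reads in the 3 knockdown libraries and 1 read in the 5 controls, a ratio per unit depth of 558 with a 95% counting interval of 99.4 to 22120. LINC02044 had 366 reads against 3 (ratio 224, interval 76 to 1091) and PRR32 had 350 against 3 (214, 72.7 to 1044). The largest fall was HS3ST2, a heparan sulfate sulfotransferase, from 270.1 ± 107 to 1.8 ± 0.609 (log2 -6.53). SHISA9 (-5.95), MROH2A (-5.52), the adhesion receptor ADGRA1 (-5.06), CCND1, the bone phosphatase PHOSPHO1 (-4.43), the huntingtin-associated protein gene HAP1 (-4.43, adjusted p = 7.30e-12) and the receptor GPR17 (-4.36) came next.

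The EWS-FLI1 activated targets had a median log2 of -1.36 at 24 h and the same counts adjusted over the list alone. Besides CCND1 and MYC, the list held STEAP1, a metalloreductase of the cell surface (log2 -2.64), and IL1RAP, an interleukin receptor subunit (-2.44). Of the repressed targets 19 were higher and 3 lower adjusted over the list alone, and IGFBP5, a binding protein of insulin-like growth factors, was at log2 3.42. Mesenchymal and extracellular matrix genes were higher, 18 of 30 against 1 lower, unchanged when adjusted over the list alone (adjusted p = 9.36e-05, adjusted p = 0.0929 with an estimated correlation), with the collagens COL3A1 and COL5A2 at log2 1.88 and 1.90. HOX genes, which pattern the body axis, rose in 20 of 33 and fell in 1 (21 higher and 1 lower adjusted over the list alone; adjusted p = 0.000103, adjusted p = 0.0929 with an estimated correlation), led by HOXC4 (1.98), HOXC6 (1.29) and HOXA13 (2.67). Interferon response and antigen presentation genes rose in 11 of 20 and fell in 1 (12 higher and 1 lower adjusted over the list alone; adjusted p = 0.000872, adjusted p = 0.167 with an estimated correlation), among them IFIT3 (1.42) and the signal transducer STAT2 (1.27).

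Mitosis genes rose at 24 h in 20 of 32 and fell in 0 (22 higher and 0 lower adjusted over the list alone; median log2 0.41, adjusted p = 9.36e-05, adjusted p = 0.838 with an estimated correlation). The centrosome kinase NEK2 rose by log2 0.95 and securin, PTTG1, by 0.65. DNA repair genes fell in 17 of 30 and rose in 1, as they did adjusted over the list alone (adjusted p = 0.000487, adjusted p = 0.498 with an estimated correlation), with the checkpoint kinase ATR at -0.80 and PALB2 at -0.73. DNA replication and E2F target genes did not pass the list test (adjusted p = 0.126), though 10 of 32 were lower and 2 higher, also adjusted over the list alone, including RFC3 (-0.89) and GINS1 (-0.89). All of these list calls held against the second-kind controls alone and in every fit with 1 library left out. Against those 3 controls, 5626 genes were higher and 5601 lower.

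By 48 h of shFLI1, 6768 genes were higher and 6661 lower, 3683 and 2886 of them at least 2-fold. DKK1 had risen from 0.187 ± 0.417 to 2351 ± 1007 (log2 10.91, SE 0.39, adjusted p = 6.01e-11), which was 6197 reads against 1 read (ratio 11710, interval 2100 to 462500). The secreted protein gene SCUBE1 rose from 9.46 ± 5.39 to 14329 ± 2207 (log2 10.58, adjusted p = 9.77e-11). MGP, an inhibitor of calcification, rose from 4.17 ± 4.72 to 3287 ± 1346 (log2 9.68), and the scavenger receptor SCARA5 by 9.29. CCND1 was at 177 ± 19.4 against 11042 ± 3895 in the controls (log2 -5.88, adjusted p = 3.02e-10).

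The other named rises at 48 h were the pentraxin PTX3 (log2 9.20), the succinate receptor SUCNR1 (8.58), the synaptotagmin SYT17 (8.33) and ARSJ (8.30). PTX3 had 2380 reads against 3 (ratio 1499, interval 512.2 to 7272), SYT17 had 1064 against 2 (1005, interval 277.5 to 8309) and SUCNR1 2459 against 9 (516, 271 to 1130). MROH2A fell by log2 6.29, ADGRA1 fell by 6.25, GPR17 fell by 6.01, PHOSPHO1 fell by 5.68, the calsyntenin CLSTN2 fell by 5.4, the neuronal vesicle protein gene NSG2 fell by 5.29 and LINC02013 fell by 5.13. All 16 named genes passed the test in every fit with 1 library left out and against second-kind controls alone, while the authors' deposited table had DKK1 at log2 0.18 (adjusted p = 0.198).

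EWS-FLI1 activated targets at 48 h fell in 35 of 42 and rose in 2 (2 higher and 36 lower adjusted over the list alone; median log2 -1.27, adjusted p = 4.21e-11, adjusted p = 0.156 with an estimated correlation), with STEAP1 at log2 -4.15 and the neuropeptide Y receptor NPY1R at -3.50. Repressed targets rose in 25 of 29 with 0 lower, and likewise adjusted over the list alone, at a median of 2.49 (adjusted p = 2.80e-10, adjusted p = 0.0202 with an estimated correlation). TPM1, a tropomyosin of actin filaments, rose from 1867 ± 89.4 to 18112 ± 3697 (log2 3.26). Mesenchymal and extracellular matrix genes rose in 25 of 30 and fell in 1 (the same adjusted over the list alone; adjusted p = 1.42e-07, adjusted p = 0.156 with an estimated correlation), with fibronectin, FN1, at 377861 ± 100570.0 against 30076 ± 4034 (log2 3.63). Interferon response and antigen presentation genes rose in 16 of 20, none being called lower (the same adjusted over the list alone; adjusted p = 0.000386, adjusted p = 0.156 with an estimated correlation). Immediate early and AP-1 genes rose in 16 of 22 and fell in 3 (the same adjusted over the list alone; adjusted p = 0.0015, adjusted p = 0.261 with an estimated correlation), with the ERK phosphatase DUSP6 at log2 5.67 and MYC at -3.27. HOX genes rose in 20 of 33 and fell in 2 (the same adjusted over the list alone; adjusted p = 0.00606, adjusted p = 0.261 with an estimated correlation).

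Mitosis genes were lower at 48 h in 31 of 32 (the same adjusted over the list alone; median log2 -1.04, adjusted p = 1.59e-10, adjusted p = 0.327 with an estimated correlation), such as the spindle checkpoint kinase BUB1B at log2 -1.68. Replication and E2F genes were lower in 29 of 32 (the same adjusted over the list alone; adjusted p = 8.27e-10, adjusted p = 0.209 with an estimated correlation), with the ribonucleotide reductase subunit RRM2 at -2.35 and GINS1 at -1.95. Repair genes fell in 27 of 30 and rose in 2 (the same adjusted over the list alone; adjusted p = 1.59e-10, adjusted p = 0.111 with an estimated correlation), the exonuclease EXO1 at -2.38. Replication-dependent histone genes, whose short messages are also a sign of RNA quality, fell in 27 of 30 and rose in 1 (1 higher and 28 lower adjusted over the list alone; adjusted p = 2.39e-08, adjusted p = 0.396 with an estimated correlation), with H2AC16 at -1.99. Glycolysis and hypoxia genes fell in 18 of 26 and rose in 6 (the same adjusted over the list alone; adjusted p = 0.022, adjusted p = 0.437 with an estimated correlation). Among these, hexokinase HK2 was at -2.76, the phosphofructokinase PFKP at -2.42 and adrenomedullin, ADM, at 4.29. The cyclin-dependent kinase inhibitor CDKN1A, on the p53 list, rose by 4.63, while the p53 list as a whole did not pass (adjusted p = 0.542).

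Mitochondrial ribosomal RNA, a sign of RNA quality, took 22.1 to 22.5 percent of reads with shFLI1 at 48 h against 16.2 to 17.98 in shScramble, and 18 to 19.9 against 15.2 to 17.8 at 24 h. The 10 most abundant genes took 28.9 to 30.5 percent against 20.6 to 22.7 at 48 h and 23.8 to 25.8 against 20.7 to 22.4 at 24 h (two-sided exact permutation p = 0.0179 each, the smallest 56 splits allow). With the CHD4 hairpins p was 0.0714 to 0.679. Centring each library on its median moved the median of all tested genes with shFLI1 at 48 h from 0.01 to -0.11, and relative to that the list calls above stood. Processed pseudogenes moved with shFLI1, with a median log2 fold change at 48 h that differed from that of protein-coding genes by -0.634, or by -0.277 against second-kind controls alone.

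Whether a fold change with shFLI1 differed between 24 and 48 h was tested gene by gene. The mitosis genes went from mostly higher to mostly lower, with a median difference of log2 -1.41 (camera adjusted p = 1.76e-41, and adjusted p = 0.0155 with an estimated correlation). All 32 of 32 members had a lower fold change at 48 h past the test. NEK2 went from 0.95 to -0.52. Repair genes differed by -0.68 (adjusted p = 7.03e-19) and replication genes by -0.81 (7.03e-19). Repressed targets rose further, by 1.62 (7.79e-15), and immediate early genes, which had not passed as a list at 24 h (adjusted p = 0.785), differed by 1.18 (2.60e-10). These calls held with an estimated correlation. In all, 3664 genes differed, 1614 with a higher and 2050 with a lower fold change at 48 h. Between shScramble libraries alone, limma called 0 genes between 48 and 24 h, with 390 at an unadjusted p under 0.05, and the authors' own table of that comparison called 2 higher and 2 lower. Against second-kind libraries alone the number of differing genes was 5772.

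**Figure D3:**
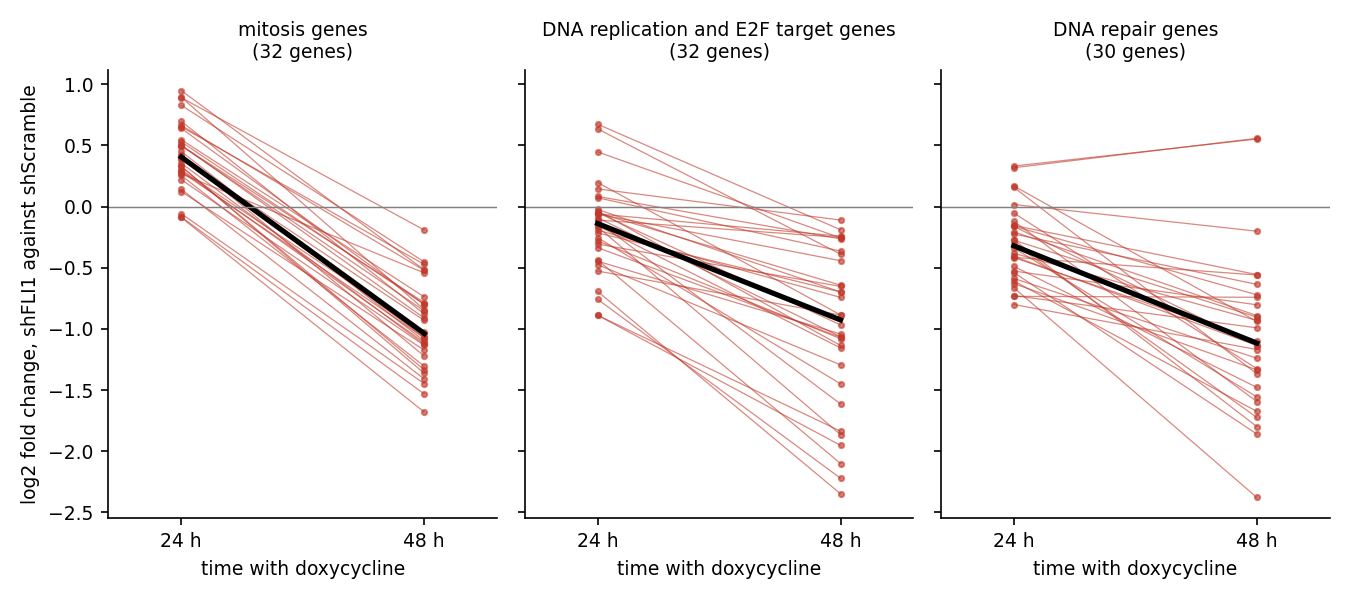
Log2 fold change with shFLI1 at 24 and 48 h of each mitosis, replication and repair gene (grey lines), with the list's median in black. The mitosis median went from 0.41 to -1.04, the replication median from -0.14 to -0.93 and the repair median from -0.32 to -1.12.

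At 24 h of CHD4 knockdown, 347 genes were higher and 306 lower with both hairpins. PPL, the cytolinker periplakin (chromosome 16, 4882507 to 4960741), rose from 16.1 ± 6.17 to 169.6 ± 69.6 with shCHD4#1 (log2 3.30, adjusted p = 5.62e-05) and 120.4 ± 38.8 with shCHD4#2 (2.85, 0.000162). MISP, a mitotic spindle protein gene, rose by log2 3.52 and 2.27, and the dehydrogenase gene DHRS2 by 2.40 and 2.61. ZNF624, a zinc finger gene, fell from 359 ± 30.9 to 156 ± 28.3 and 174 ± 56.4 (log2 -1.21 and -1.08), and EFR3B by -1.72 and -1.49. With shCHD4#1 1095 genes were higher and 1290 lower, 542 and 181 of them at least 2-fold, and with shCHD4#2 851 and 1474 (322 and 220). Independent lists would share 44.3 higher and 90.4 lower genes. The hairpins also share controls. Simulated unchanged groups shared 0, a value that leaves out pairs and library kinds, and other splits of the libraries shared up to 14 in all. With split controls the shared genes averaged 159 higher (range 111 to 253) and 111 lower (68 to 215). With library kind as a term higher and lower genes numbered 714 and 807 for both, 1994 and 2537 for shCHD4#1 and 1962 and 2722 for shCHD4#2, and in the second kind alone, with 1 library per hairpin, 98 and 65, 456 and 554, and 231 and 520. A fit of only the groups compared gave 186 and 151 for both, and the authors' deposited tables gave 31 and 4. Without replicate 2 of shCHD4#1 counts were 201 and 141 for both and 424 and 484 for that hairpin, and without that of shCHD4#2 156 and 143, and 273 and 613. Without shScramble replicate 3 197 genes were lower with both, and without replicate 3 of each hairpin 684 were higher with shCHD4#1 and 547 with shCHD4#2.

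Named rises of antisense, non-coding and pseudogene transcripts at 24 h, whose source is uncertain without a stated strand setting, were TSPEAR-AS2 (log2 3.47 with shCHD4#1 and 3.22 with shCHD4#2), LINC00624 (2.87 and 3.31), the pseudogene AACSP1 (3.91 and 2.87) and CCDC144NL-AS1 (3.05 and 2.85). RIMBP3B and RIMBP3C, near-identical copies, are uncertain and not described further. The activin subunit INHBE (log2 1.99 and 2.56), the GTPase RHOB (-1.42 and -1.28), ZNF524 (-1.16 and -1.05) and the steroid dehydrogenase HSD17B2 (-1.20 and -1.01) were also named. Their calls hung on single libraries. Without replicate 2 of shCHD4#1 the adjusted p was 0.128 for INHBE and 0.108 for RHOB, without its replicate 3 it was 0.0859 for INHBE, and without its replicate 1 it was 0.059 for ZNF524. Without replicate 2 of shCHD4#2 it was 0.144 for RHOB, 0.145 for HSD17B2 and 0.134 for ZNF524. Without its replicate 1 it was 0.0624 for RHOB and 0.0798 for ZNF524, and without shScramble replicate 1 it was 0.0501 for RHOB with shCHD4#2. With a replicate block ZNF524 was at log2 -0.95 with shCHD4#2 (adjusted p = 0.0536). In the authors' deposited tables DHRS2, EFR3B, RHOB, ZNF524 and HSD17B2 did not pass with either hairpin, INHBE not with shCHD4#1 and ZNF624 not with shCHD4#2, at adjusted p of 0.106 to 1.

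At 24 h of CHD4 knockdown, replication and E2F genes fell in 6 of 32 with shCHD4#1 and 13 with shCHD4#2, or 12 and 21 adjusted over the list alone, with none higher. For them camera's adjusted p was 5.89e-06 and 1.65e-10, and adjusted p = 0.733 and 0.582 with an estimated correlation. The transcription factor E2F2 was at log2 -0.80 and -0.67. Mitosis genes fell in 4 and 8 of 32, or 6 and 11 adjusted over the list alone, none being higher. Here camera's adjusted p was 0.000337 and 4.75e-06, and adjusted p = 0.757 and 0.615 with an estimated correlation. Repair genes fell in 4 of 30 with shCHD4#1 and in 3 with shCHD4#2, where 1 rose. Adjusted over the list alone 6 and 4 were lower and 1 was higher with shCHD4#2. Of this list camera's adjusted p was 0.00104 and 0.00777, and adjusted p = 0.733 and 0.592 with an estimated correlation. RAD51D, a recombinase paralogue, was at log2 -0.84 with shCHD4#1. The E2F2 call with shCHD4#2 ended without its replicate 2 (adjusted p = 0.0802), the mitosis call with shCHD4#1 without its replicate 1 (0.0605) and the repair call with shCHD4#2 without its replicate 1 (0.0932). With fry the replication and mitosis calls with shCHD4#1 (adjusted p = 0.0699 and 0.194) and the mitosis call with shCHD4#2 (0.0917) ended. Among second-kind libraries alone the mitosis call with shCHD4#1 (adjusted p = 0.0691), the repair call with shCHD4#2 (0.176) and the calls of E2F2 (0.107 and 0.318) and DHRS2 (0.206 and 0.128) ended.

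Cholesterol synthesis genes were lower at 24 h in 2 of 24 with shCHD4#1, where 1 was higher, and in 11 with shCHD4#2. The counts were 4 lower and 2 higher, then 11 lower, adjusted over the list alone. For the 2 hairpins camera's adjusted p was 0.0259 and 3.58e-06, and adjusted p = 0.757 and 0.582 with an estimated correlation. Squalene epoxidase, SQLE, fell by log2 0.63 with shCHD4#1 (adjusted p = 0.00307) and fell by 0.65 with shCHD4#2 (0.00256). The cholesterol list call with shCHD4#1 ended with a replicate block (adjusted p = 0.153), fry (0.194), kind as a term (0.0816), within the first library kind (0.419), and without shScramble replicate 3, 4 or 5 or shCHD4#1 replicate 1 (0.0513, 0.0623, 0.0721 and 0.193). EWS-FLI1 activated targets fell in 12 of 42 with shCHD4#2 (0 higher and 16 lower adjusted over the list alone; adjusted p = 3.55e-05, adjusted p = 0.582 with an estimated correlation), NPY1R at -1.03. With shCHD4#1 their list did not pass (adjusted p = 0.159). HOX genes fell in 5 of 33 with shCHD4#1 (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.00995, adjusted p = 0.505 with an estimated correlation), a call lost among second-kind libraries (adjusted p = 0.19) and with kind as a term (0.0559). Germline genes, normally silent outside testis and ovary, were higher with shCHD4#2 as a list, though only 1 of 12 passed alone (4 higher and 0 lower adjusted over the list alone; adjusted p = 0.0124, adjusted p = 0.558 with an estimated correlation). Apoptosis regulators were lower with shCHD4#2 in 3 of 27 (1 higher and 11 lower adjusted over the list alone; adjusted p = 0.0247, adjusted p = 0.582 with an estimated correlation). The germline call ended without shCHD4#2 replicate 2 (adjusted p = 0.0834) and within the first kind (0.114). The apoptosis call ended without shScramble replicate 5 (0.102) or shCHD4#2 replicate 1 or 2 (0.112 and 0.051), with a replicate block (0.0599), kind as a term (0.0943), and within the second and first kinds (0.211 and 0.0596).

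At 48 h of CHD4 knockdown, 1052 genes were higher and 1312 lower with both hairpins. PPL was at 385 ± 42.4 with shCHD4#1 and 208 ± 76.6 with shCHD4#2 against 11.9 ± 3.75 in shScramble (log2 4.95 and 4.0), and DHRS2 at log2 3.79 and 4.49. CNIH2, an auxiliary subunit of AMPA receptors, fell by 2.12 with shCHD4#1 and fell by 2.39 with shCHD4#2. NSG2 was at -1.84 and -2.28, and ZNF624 at -1.71 and -1.66. With shCHD4#1 2707 genes were higher and 3258 lower, 1049 and 667 at least 2-fold. With shCHD4#2 the counts were 3688 and 4276 (1274 and 1181). Independent lists would share 475 and 663, simulated unchanged groups shared 0, other splits of the libraries shared up to 599, and split controls gave 654 (547 to 803) and 792 (606 to 1066). Within the first kind alone, of 2 libraries a group, 310 and 175 were shared, with 604 and 611 for shCHD4#1 and 1369 and 1605 for shCHD4#2. The authors' deposited tables gave 182 and 59 for both. Without replicate 2 of each hairpin 1684 and 2015 genes passed with shCHD4#1, and 2333 were higher with shCHD4#2.

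Transcripts of these uncertain kinds that were named as higher at 48 h were CCDC144NL-AS1 (log2 5.45 with shCHD4#1 and 5.44 with shCHD4#2), TSPEAR-AS2 (4.51 and 4.61), LINC00408 (5.43 and 4.38), the nearby pseudogene ANKRD20A9P (4.25 and 4.02), AACSP1 (5.35 and 3.76) and LINC00624 (3.68 and 4.43). The complement-related C1QL1 (-2.15 and -1.88), the carbonyl reductase CBR3 (-1.63 and -1.72), the kinase SGK1 (-1.62 and -2.17) and RCAN3, a regulator of calcineurin (-1.53 and -1.81), fell with both. None of these 10 genes lost its call in a fit with 1 library left out. Within the first library kind alone, of 2 libraries a group, C1QL1 (adjusted p = 0.0665 and 0.0891) and, with shCHD4#1, DHRS2 (0.0732), LINC00624 (0.0606), CNIH2 (0.0526), SGK1 (0.0688) and RCAN3 (0.0741) did not pass. Within the second kind PPL (0.0638) and AACSP1 (0.119) did not pass with shCHD4#2. In the authors' deposited tables SGK1 did not pass with shCHD4#1 (adjusted p = 0.204).

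Cholesterol synthesis genes at 48 h fell in 7 of 24 with shCHD4#1 and 21 with shCHD4#2, or 7 and 23 adjusted over the list alone, at medians of log2 -0.36 and -1.16. Their camera's adjusted p was 0.000655 and 1.43e-11, and adjusted p = 0.61 and 0.326 with an estimated correlation. SQLE (chromosome 8, 124998497 to 125022283) fell from 32068 ± 4878 to 15683 ± 2581 and 11292 ± 1079 (log2 -1.03 and -1.5). The synthase HMGCS1 fell from 6051 ± 1005 to 1744 ± 245 with shCHD4#2 (log2 -1.79, adjusted p = 2.39e-06). With shCHD4#1 HMGCS1 was at -0.62 (adjusted p = 0.0102), a call lost without replicate 1 of that hairpin (0.0632) and with a replicate block (log2 -0.50, adjusted p = 0.0743). Replication and E2F genes fell in 18 and 24 of 32, or 20 and 25 adjusted over the list alone, the helicase subunit MCM6 at -0.51 and -0.68. For replication camera's adjusted p was 8.36e-07 and 6.76e-09, and adjusted p = 0.587 and 0.326 with an estimated correlation. Mitosis genes fell in 20 and 18 of 32, or 24 and 22 adjusted over the list alone, the kinase AURKB at -0.68 and -1.14. For mitosis camera's adjusted p was 1.41e-08 and 5.20e-07, and adjusted p = 0.61 and 0.564 with an estimated correlation. Repair genes fell in 12 and 15 of 30 and rose in 1 and 2. Adjusted over the list alone 15 and 17 were lower and 1 and 3 higher. For repair camera's adjusted p was 0.000655 and 0.00714, and adjusted p = 0.587 and 0.564 with an estimated correlation.

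EWS-FLI1 activated targets fell at 48 h in 13 of 42 with shCHD4#1, where 1 rose, and in 28 with shCHD4#2, at medians of log2 -0.17 and -0.66. The counts of lower genes were 13 and 30 and of higher genes 1 and 0 adjusted over the list alone. For activated targets camera's adjusted p was 0.0154 and 4.86e-09, and adjusted p = 0.61 and 0.326 with an estimated correlation. NPY1R fell from 2309.5 ± 173 to 1002 ± 60.4 and 751 ± 213. Repressed targets rose with shCHD4#2 in 11 of 29 and fell in 1 (the same adjusted over the list alone; adjusted p = 0.0144, adjusted p = 0.326 with an estimated correlation). Immediate early genes rose with that hairpin in 8 of 22 and fell in 2 (the same adjusted over the list alone; adjusted p = 0.0472, adjusted p = 0.564 with an estimated correlation). The immediate early call ended with a replicate block (adjusted p = 0.0529), median centring (0.0519), and without shScramble replicate 1, 3 or 5 or shCHD4#2 replicate 3 (0.0585, 0.0568, 0.0633 and 0.173). Germline genes rose in 4 of 12 with shCHD4#1, where 1 fell, and in 7 with shCHD4#2. The rises were 5 and 8, with 1 fall with shCHD4#1, adjusted over the list alone. For germline genes camera's adjusted p was 0.036 and 0.00714, and adjusted p = 0.587 and 0.182 with an estimated correlation. CTCFL, a testis paralogue of CTCF, rose by 2.12 and 1.40, and the cancer-testis antigen MAGEC2 by 3.23 and 1.64. The germline call with shCHD4#1 ended without its replicate 1 (adjusted p = 0.0543) and within the second and first library kinds (0.0642 and 0.0651). HOX genes fell with shCHD4#1 in 13 of 33 and rose in 2 (2 higher and 15 lower adjusted over the list alone; adjusted p = 0.00446, adjusted p = 0.587 with an estimated correlation), not so among second-kind libraries alone (adjusted p = 0.0642). Histone genes fell with shCHD4#1 in 8 of 30 and rose in 3 (3 higher and 9 lower adjusted over the list alone; adjusted p = 0.0118, adjusted p = 0.682 with an estimated correlation), a call lost with a replicate block (adjusted p = 0.0737), fry (0.176), and within the first kind (0.93). Within that kind, of 2 libraries a group, the activated target and cholesterol calls with shCHD4#1 (adjusted p = 0.197 and 0.0848) and the repressed target and immediate early calls with shCHD4#2 (0.117 and 0.391) also ended.

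The CHD4 hairpins differed from each other in many genes although CHD4 itself did not differ past the test (log2 0.21 for shCHD4#1 minus shCHD4#2 at 48 h, adjusted p = 0.164; -0.04 at 24 h, 0.902). CCN2, a matricellular growth factor, fell from 315 ± 103 to 72.7 ± 15 with shCHD4#1 (log2 -2.06, adjusted p = 0.000251) and rose to 1090.1 ± 528 with shCHD4#2 (1.72, 0.000634). TP53INP1, a stress-induced protein gene, rose from 472 ± 95 to 1926 ± 186 with shCHD4#1 (log2 2.04) and fell to 216 ± 11.7 with shCHD4#2 (-1.10). TNFRSF12A, the receptor of TWEAK, was at 254 ± 31.2 and 1643 ± 472 against 129.9 ± 14.1 (log2 0.96 and 3.61). The tight junction claudin CLDN4 was at 3.03 and 1.5, and the apoptosis activator BMF at 0.99 and -0.94. Within the first kind alone CCN2 with shCHD4#2 (adjusted p = 0.126) and TNFRSF12A and BMF with shCHD4#1 (0.0985 and 0.177) did not pass.

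Between the hairpins, 2022 genes differed at 24 h, 1181 of them higher with shCHD4#1, or 3475 with a replicate block and 4455 with kind as a term, and 7963 differed at 48 h, 4046 higher with shCHD4#1. Within the second and first library kinds alone the 24 h count was 283 and 1793, and at 48 h it was 6553 and 2889. The 24 h count was 874 and 1285 without replicates 2 and 3 of shCHD4#1, 991 without replicate 2 of shCHD4#2 and 1245 in a fit of only the groups compared. At 48 h both hairpins called 2869 genes against shScramble, 505 of them in opposite directions. Activated targets at 48 h were higher with shCHD4#1 than with shCHD4#2 in 21 of 42 and lower in 2 (22 higher and 2 lower adjusted over the list alone; adjusted p = 0.000158, adjusted p = 0.62 with an estimated correlation). Cholesterol genes were higher in 18 of 24 against 1 (the same adjusted over the list alone; adjusted p = 2.01e-05, adjusted p = 0.62 with an estimated correlation). Repressed targets were lower with shCHD4#1 in 11 of 29 against 2 higher (the same adjusted over the list alone; adjusted p = 0.00485, adjusted p = 0.62 with an estimated correlation). So were immediate early genes in 13 of 22 against 2 (the same adjusted over the list alone; adjusted p = 0.00771, adjusted p = 0.62 with an estimated correlation) and cytosolic ribosomal protein genes in 21 of 40 (0 higher and 27 lower adjusted over the list alone; adjusted p = 5.54e-07, adjusted p = 0.622 with an estimated correlation). Epithelial genes were higher in 5 of 10 (the same adjusted over the list alone; adjusted p = 0.0287, adjusted p = 0.62 with an estimated correlation) and mitochondrially encoded genes in 5 of 15 (0 higher and 0 lower adjusted over the list alone; adjusted p = 0.036, adjusted p = 0.62 with an estimated correlation). The mitochondrial call ended in the second kind (0.178) and without replicate 1 or 3 of shCHD4#1 or 2 of shCHD4#2 (0.0552, 0.0743 and 0.167). Histone genes passed, as lower with shCHD4#1, with a replicate block (0.0318, main fit 0.0966). At 24 h neuronal genes were higher with shCHD4#1 in 4 of 24 (6 higher and 0 lower adjusted over the list alone; adjusted p = 0.00272, adjusted p = 0.421 with an estimated correlation), activated targets in 6 of 42 (the same adjusted over the list alone; adjusted p = 0.0399, adjusted p = 0.714 with an estimated correlation) and cholesterol genes in 2 of 24 (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.0399, adjusted p = 0.84 with an estimated correlation), and ribosomal protein genes were lower in 1 of 40 (the same adjusted over the list alone; adjusted p = 0.0145, adjusted p = 0.84 with an estimated correlation). All but the neuronal call ended with fry (0.122, 0.297 and 0.558). Without replicate 1 of shCHD4#1 the activated target and ribosomal calls ended (0.0961 and 0.0937), without its replicate 2 the cholesterol and ribosomal calls (0.0557 and 0.0557) and without its replicate 3 the cholesterol call (0.218). Without replicate 2 of shCHD4#2 the activated target and cholesterol calls ended (0.112 and 0.118) and without its replicate 3 the ribosomal call (0.216). The activated target call also ended in the second kind (0.134) and the cholesterol call in the first (0.139) and with kind as a term (0.0583). CCND1 was higher with shCHD4#1 by log2 1.7 at 24 h (adjusted p = 0.000861) and by 2.47 at 48 h (3.65e-05).

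**Figure D4:**
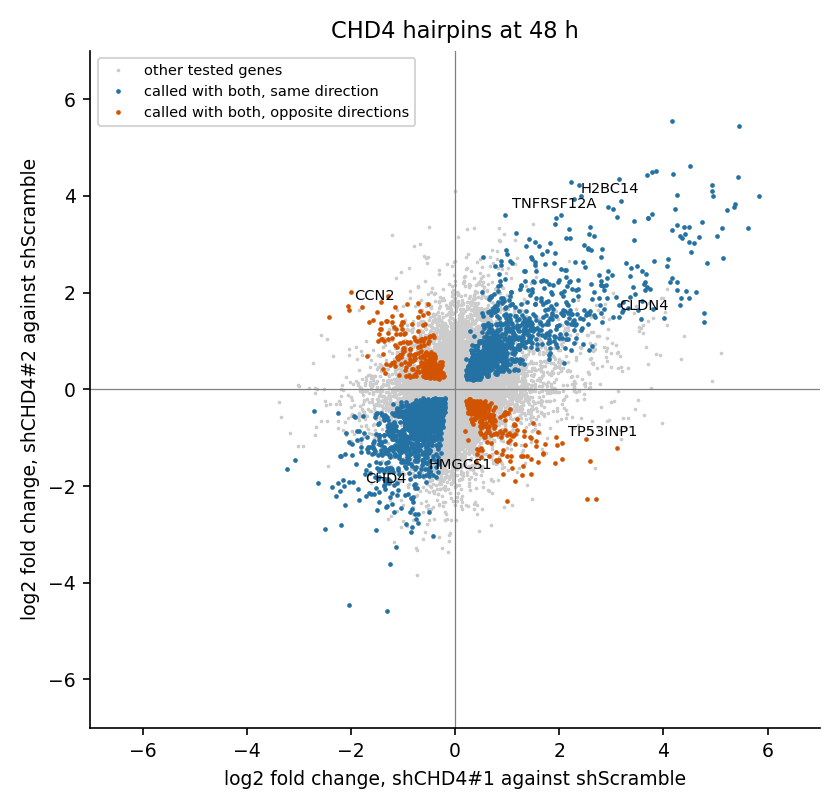
Log2 fold change against shScramble at 48 h with shCHD4#1 (horizontal) and shCHD4#2 (vertical) of the 2869 genes called with both hairpins. CHD4 lies at -1.86 and -2.07, CCN2 at -2.06 and 1.72, and 505 genes lie in the quadrants of opposite sign.

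With shCHD4#2 283 genes differed between 24 and 48 h, or 62 with a replicate block, 91 higher and 192 lower at 48 h. TNFRSF12A went from log2 1.51 to 3.61, HMGCS1 from -0.85 to -1.79 and SQLE from -0.65 to -1.5. Cholesterol genes differed by a median of -0.81 with shCHD4#2 (camera adjusted p = 1.45e-20, and adjusted p = 0.105 with an estimated correlation). With shCHD4#1 limma called 0 genes, with 900 at an unadjusted p under 0.05, where edgeR called 1 and DESeq2 3. The shCHD4#2 count was 1404 without 48 h replicate 1 of that hairpin and 21 without its 48 h replicate 2, and within the first library kind it was 0 by limma.

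At 48 h, 537 genes were higher with both CHD4 hairpins and shFLI1 and 660 lower, against 339 and 416 for independent lists, while 171 were higher with CHD4 hairpins and lower with shFLI1 and 285 the reverse, against 333 and 422. At 24 h the same-direction counts were 139 and 70 against 83.9 and 68.8, and the opposite ones 48 and 80 against 78.0 and 74.0. NPY1R, STEAP1, NSG2 and SQLE were among the genes lower with shFLI1 and both CHD4 hairpins at 48 h, SQLE at log2 -0.49 with shFLI1 (adjusted p = 0.0131). Controls are shared. With these split into 2 and 3, 48 h counts averaged 365 higher in both. Independent lists gave 227, exceeded in 20 of 20 assignments. Lower in both averaged 454 against 280 (19 of 20). At 24 h they averaged 68.8 higher against 52.7 (19 of 20) and 36.1 lower against 39.1 (8 of 20). The covariance of fold changes between shFLI1 and shCHD4#2 was 0.231 at 48 h (0.0294 in simulated unchanged groups, 0.199 with split controls, range 0.0690 to 0.255). With shCHD4#1 it was 0.118 (0.0294 simulated, 0.0861 split, -0.0322 to 0.134). At 24 h the values were 0.0570 (0.025, 0.0237, -0.0372 to 0.0613) and 0.0438 (0.0251, 0.0105, -0.0662 to 0.0436). The split ranges of both 24 h values and of the 48 h value with shCHD4#1 hold 0. Simulated values leave out pairs and library kinds, and split controls differ in kind. Correlations with shCHD4#2 and shCHD4#1 were 0.240 and 0.129 at 48 h and 0.133 and 0.0923 at 24 h. The simulated 0.373 to 0.376 is fixed by group sizes and cannot judge them. Among second-kind libraries alone, 1 per hairpin, covariances were 0.324 and 0.220 at 48 h and 0.104 and 0.133 at 24 h.

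Epithelial genes, markers of another cell type, which SK-N-MC should largely lack, rose with shCHD4#1 at 24 h in 1 of 10 (4 higher and 1 lower adjusted over the list alone; median log2 0.47, adjusted p = 0.0378, adjusted p = 0.505 with an estimated correlation), led by CLDN4 from 18.9 ± 6.39 to 117 ± 54.5. That call ended with a replicate block (adjusted p = 0.0962), no filter (0.227), kind as a term (0.0679), within the first library kind (0.356), and without shScramble replicate 3 or 5 or shCHD4#1 replicate 3 (0.0513, 0.0721 and 0.0938). The epithelial list did not pass with shCHD4#2 at 24 h (adjusted p = 0.868), with shCHD4#1 or shCHD4#2 at 48 h (0.0641 and 0.709), or with shFLI1 at either time (0.961 and 0.997). With shCHD4#1 at 48 h it was higher with fry (0.00383), no filter (0.0366) and in the second kind alone (0.045). With shFLI1 at 48 h its median was -0.45 while its mean was 0.34. Haematopoietic and endothelial genes did not pass camera in any comparison with shScramble, with adjusted p of 0.997, 0.217 and 0.65 for shFLI1, shCHD4#1 and shCHD4#2 at 24 h and 0.259, 0.454 and 0.372 at 48 h. Fry called them lower at 48 h with shFLI1 (4 of 8 lower and 1 higher, adjusted p = 5.86e-05) and shCHD4#2 (3 of 8, 0.00658). Mitochondrially encoded genes did not pass camera either (0.589, 0.593 and 0.887, then 0.542, 0.106 and 0.405), but were higher with shCHD4#1 at 48 h with a replicate block (0.0194) and in the second kind alone (0.0496). Ribosomal protein genes were lower with shCHD4#1 at 24 h as a list, with 1 of 40 passing alone (the same adjusted over the list alone; adjusted p = 0.00333, adjusted p = 0.839 with an estimated correlation), and at 48 h in 14 (0 higher and 15 lower adjusted over the list alone; adjusted p = 7.95e-07, adjusted p = 0.61 with an estimated correlation). With shFLI1 at 48 h they were lower in 14 against 1 higher (0 higher and 8 lower adjusted over the list alone; adjusted p = 0.0219, adjusted p = 0.772 with an estimated correlation). The 24 h call ended with a replicate block (adjusted p = 0.138), fry (0.403), kind as a term (0.0795), within either kind (0.0665 and 0.302), and without shScramble replicate 5 or shCHD4#1 replicate 1 (0.0866 and 0.0605). The shFLI1 call ended with fry (0.0621) and without shScramble replicate 3 or shFLI1 replicate 3 (0.0526 and 0.242). With shCHD4#2 the ribosomal list did not pass at 24 or 48 h (0.996 and 0.32). The histone list did not pass with shCHD4#2 at 48 h (adjusted p = 0.755).

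The remaining lists did not pass camera in any comparison with shScramble. Its adjusted p for shFLI1, shCHD4#1 and shCHD4#2 was 0.961, 0.0913 and 0.65 at 24 h and 0.274, 0.0764 and 0.709 at 48 h for NuRD complex subunits. In that order it was 0.589, 0.126, 0.092, 0.987, 0.628, 0.276 for neuronal genes, 0.584, 0.757, 0.996, 0.386, 0.737, 0.991 for striated muscle genes, 0.589, 0.217, 0.967, 0.542, 0.419, 0.497 for p53 target genes and 0.788, 0.833, 0.783, 0.47, 0.141, 0.755 for ATF4 and unfolded protein response genes. These lists held single genes that moved strongly with shFLI1 at 24 h, such as the vesicle protein gene SYT4 (log2 -4.65), the calcium channel RYR2 (-2.53) and CDKN1A (3.31). Cholesterol synthesis genes did not pass with shFLI1 (0.589 at 24 h and 0.99 at 48 h), nor did germline genes (0.589 and 0.542) or apoptosis regulators (0.785 and 0.602).

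**Figure D5:**
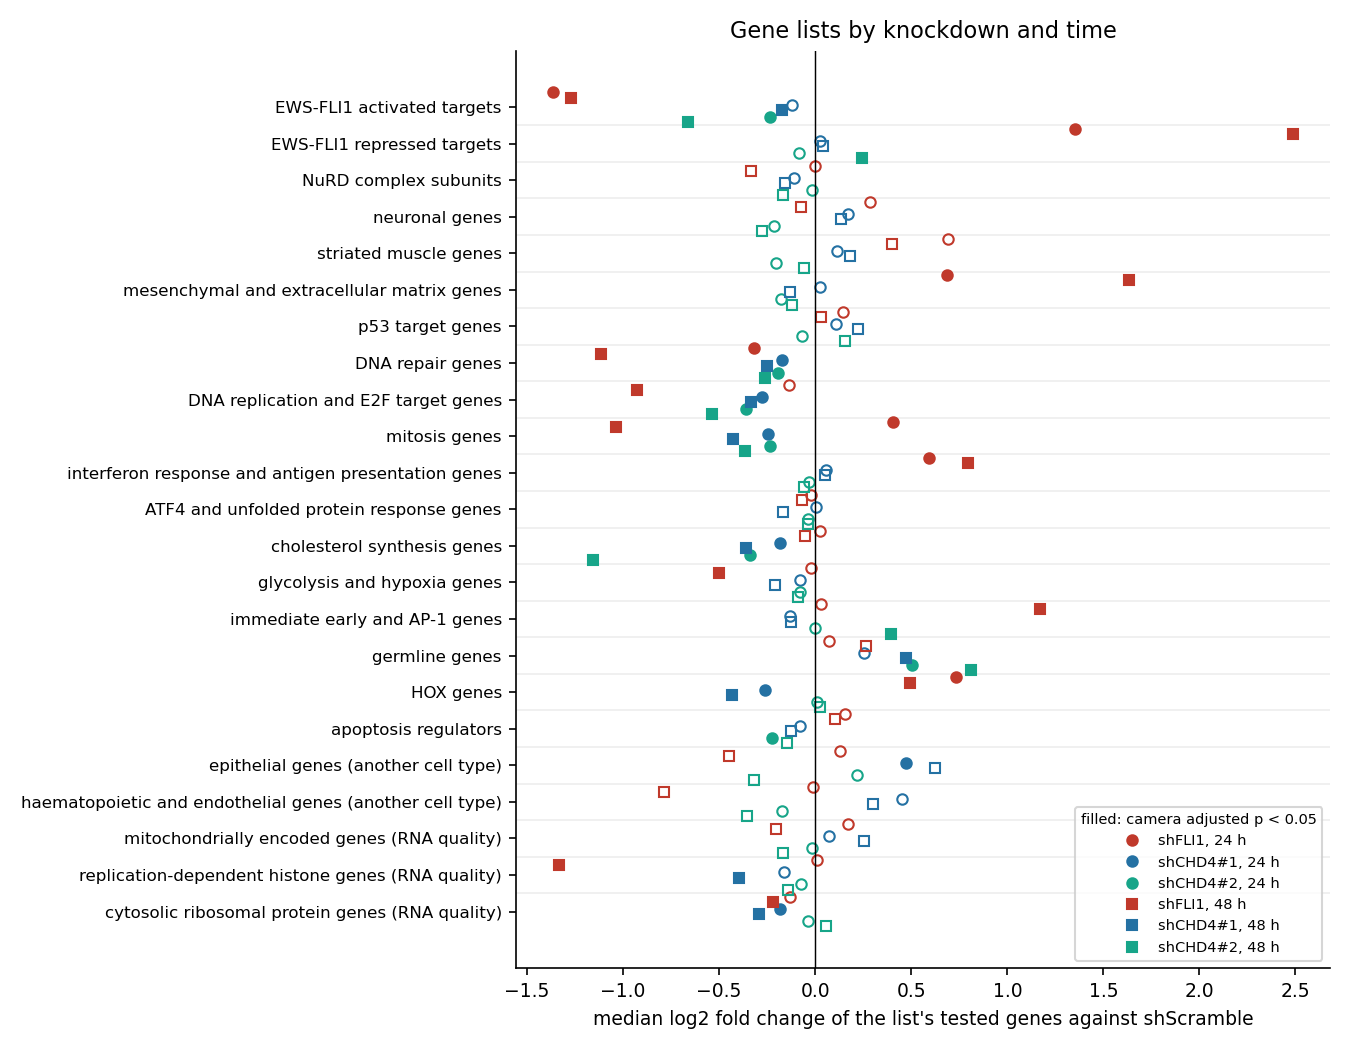
Median log2 fold change of each of the 23 gene lists against shScramble by knockdown and time, with filled points for lists that passed camera at an adjusted p of 0.05. EWS-FLI1 repressed targets reach 2.49 with shFLI1 at 48 h.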

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

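Comparisons of the deposited 24 h table with other contrasts and fits within 1 library kind were chosen after its values were seen. Other tests here were planned. Of 202 shScramble groups of 5 among named genes, 15 held a library far from the other 4 (gap over range above 0.71). Chance gives this in about 1 in 20 groups, or 10.1 of 202. This rate does not cover DKK1 and SYT17, with 1 or 2 reads, all in 1 control. The 24 h cases were DKK1 and SYT17 (ratio 1), GPR17 (0.8205), HOXC4 (0.754), ANKRD20A9P (0.749), RCAN3 (0.733) and PHOSPHO1 (0.725). At 48 h they were DKK1 (1), SYT17 (1), NSG2 (0.8615), MISP (0.847), ANKRD20A9P (0.813), DHRS2 (0.794), LINC00624 (0.725) and LINC02013 (0.72).

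In 46 named genes the fold change differed between the times past the test. With shFLI1 it was higher at 48 h than at 24 h for MGP (by log2 5.56), PTX3 (5.47), SCUBE1 (5.17), SCARA5 (4.55), DKK1 (4.43), SYT17 (3.545), SUCNR1 (3.38), ARSJ (1.73) and SIPA1L2 (1.75). SHISA9 fell less far at 48 h (1.92), and HS3ST2 (4.415) went from log2 -6.53 to -2.12, where it did not pass (adjusted p = 0.207). FN1 rose further by 2.29, TPM1 by 1.82, COL5A2 by 1.35 and COL3A1 by 1.07, as did DUSP6 (3.85), ADM (1.64), CDKN1C (0.79) and STAT2 (0.60), and BCL2L11 differed by 1.47. Fold changes were lower at 48 h for CLSTN2 (-2.40), LINC02013 (-2.10), NSG2 (-1.91), GPR17 (-1.65), STEAP1 (-1.51), PHOSPHO1 (-1.25), CCND1 (-1.21), ADGRA1 (-1.19), BCL11B (-0.87), IL1RAP (-0.59) and PFKP (-1.29), and CDH10 rose less (-1.82). Also lower were H2AC16 (-1.87), EXO1 (-1.71), RRM2 (-1.65), BUB1B (-1.59), NEK2 (-1.47), PTTG1 (-1.125), GINS1 (-1.06) and ATR (-0.37). With shCHD4#2 the differences were 2.59 for CCDC144NL-AS1, 2.11 for TNFRSF12A, -1.07 for RCAN3, -0.94 for HMGCS1, -0.85 for SQLE and -0.80 for FCGRT.

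Lists differed between the times in 25 cases, given as the median log2 difference with 2 adjusted p, the first camera's own and the other that with an estimated correlation. With shFLI1 they were mitosis -1.41 (adjusted p = 1.76e-41 and 0.0155), histone -1.38 (4.08e-16 and 0.172), haematopoietic -0.89 (0.00135 and 0.0435), replication -0.81 (7.03e-19 and 0.0453), repair -0.68 (7.03e-19 and 0.00502), mitochondrial -0.54 (0.0326 and 0.434), activated target -0.41 (2.55e-05 and 0.193), glycolysis -0.29 (0.00338 and 0.376) and NuRD genes -0.25 (0.0163 and 0.376). Higher at 48 h were repressed targets 1.62 (adjusted p = 7.79e-15 and 0.000354), immediate early 1.18 (2.60e-10 and 0.0036), matrix 0.80 (6.87e-10 and 0.0201) and interferon genes 0.39 (0.0144 and 0.193). With shCHD4#1 they were histone -0.23 (adjusted p = 0.0244 and 0.648), mitosis -0.20 (1.46e-07 and 0.64), cholesterol -0.20 (6.38e-05 and 0.64), ATF4 -0.17 (0.00602 and 0.64), HOX -0.13 (0.0244 and 0.64), ribosomal -0.11 (0.00144 and 0.64) and activated target genes -0.089 (0.00602 and 0.64). With shCHD4#2 they were cholesterol -0.81 (adjusted p = 1.45e-20 and 0.105), activated target -0.40 (2.94e-09 and 0.133), repressed target 0.42 (0.000348 and 0.105), immediate early 0.37 (0.00336 and 0.204) and mitosis genes -0.14 (0.00336 and 0.868). Drawn splits of the libraries cannot decide whether chance gives the number of genes that differed between the times. Labels were drawn at each time apart, so a draw can keep a knockdown at 1 time only and turn its effect into a difference. With shFLI1 8 of 100 splits gave at least the real 3664 (highest other 7309), and with shCHD4#2 8 of 100 gave at least 283 (4258). With shCHD4#1 the real count of 0 fixes the outcome at 100 of 100 (5544), which decides nothing. Among second-kind libraries alone shFLI1 gave 5772 genes, and among first-kind libraries shCHD4#2 gave 0 by limma.

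The deposited table named for shFLI1 against shScramble at 24 h held fold changes that correlated at 0.991 across 14216 genes with shScramble at 48 h minus shScramble at 24 h, with a median absolute difference of log2 0.00315. Genes are not independent replicates. With the comparison in its name the correlation was 0.240, where the other 5 tables reached 0.935 to 0.979 with theirs. A different shrinkage of the same comparison is argued against by that 0.240, so the table holds another contrast than its name says (0.991). Which step went wrong stays open, and no biological explanation was tested.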

How the results depend on the processing

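Library kind as a term and fits of the second or first kind alone were chosen after seeing the data, and all other alternatives were planned. Of 854 alternative values of 39 counts and covariances, 697 stayed within 1.5 times the main count or within the spread of the main covariance, and 157 moved. Of 11838 values for 546 single genes and lists, 10895 stayed on their side of the threshold and in their direction, 933 lost the call, 8 gained one and 2 reversed. EWSR1 with shFLI1 at 24 h, at log2 -0.07, was the one that reversed, to 0.12 with quantile normalisation and 0.0071 with a replicate block. Counts of called genes with shFLI1 at 24 h stayed within 1.5 times under all alternatives but the fold minimum, and at 48 h under all but that and the authors' table. With 1 library left out they ranged from 4038 to 5117 higher and 3733 to 4912 lower at 24 h and from 6070 to 6774 and 6045 to 6738 at 48 h. The authors' tables gave no value for shFLI1 at 24 h, for differences between hairpins or times, or for lists, and the first kind holds no shFLI1 library. Lists called higher and lower were 5 and 2 with shFLI1, 1 and 6 with shCHD4#1 and 1 and 6 with shCHD4#2 at 24 h, and 5 and 7, 1 and 8, and 3 and 5 at 48 h. Where a value below moved, the cause was not tested unless named. Depth limits the genes under a mean of 10, which were not tested. Simulations mostly missed changes of log2 0.5, but changed few genes, so rates may differ.

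A minimum change of 2-fold leaves fewer genes by construction. With it, higher and lower genes numbered 2266 and 1603 with shFLI1, 542 and 181 with shCHD4#1, 322 and 220 with shCHD4#2 and 170 and 19 with both hairpins at 24 h, and 3683 and 2886, 1049 and 667, 1274 and 1181, and 370 and 158 at 48 h. The hairpins then differed in 541 and 2786 genes, shFLI1 and the hairpin mean in 4435 and 6680, and the times in 1667 with shFLI1 and 144 with shCHD4#2. The authors' tables, apparently tested against a minimum, called 129 and 63 with shCHD4#1, 59 and 88 with shCHD4#2 and 31 and 4 with both at 24 h, and 3238 and 2602 with shFLI1, 617 and 331, 705 and 838, and 182 and 59 at 48 h. With shCHD4#1 the share of higher genes was 67.2 and 65.1 percent there, against 45.9 and 45.4. They ended the call in 199 of 394 gene results, among them E2F2, MCM6 and BMF with both hairpins at 48 h. The first kind alone ended it in 128 of 285 and the second in 78 of 496.

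Library kind moved most counts at 24 h. With kind as a term they were 1994 and 2537 for shCHD4#1, 1962 and 2722 for shCHD4#2, 714 and 807 for both and 4455 between hairpins, with time differences of 1 and 808 genes for shCHD4#1 and shCHD4#2. Lists called were then 5 lower with shFLI1, 0 higher and 3 lower with shCHD4#1 and 2 higher with shCHD4#2 at 24 h. In the second kind alone, with 1 library per CHD4 hairpin, assumed to vary like the other groups, counts in that order were 456 and 554, 231 and 520, 98 and 65, and 283 between hairpins, and 5772 genes differed between times with shFLI1. Lists were 4 lower with shFLI1, 2 higher and 3 lower with shCHD4#1 and 2 higher with shCHD4#2 at 24 h, and 2 higher with shCHD4#1 at 48 h. Covariances with shFLI1 there were 0.133 for shCHD4#1 and 0.104 for shCHD4#2 at 24 h and 0.220 and 0.324 at 48 h. In the first kind alone, with 2 libraries a group, 48 h counts were 604 and 611, 1369 and 1605, 310 and 175 for both, and 2889 between hairpins, the time difference with shCHD4#2 was 0 by limma, and lists with shCHD4#1 were 0 higher at 24 h and 0 higher and 5 lower at 48 h. A fit of only the groups compared, which has fewer samples, gave 707 and 792, 418 and 849, 186 and 151, and 1245 between hairpins at 24 h, and 52 for the time difference with shCHD4#2.

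A replicate block gave 3475 genes between hairpins at 24 h, 62 for the time difference with shCHD4#2, and 0 lists higher with shCHD4#1 at 24 h and 2 at 48 h. It ended 7 of 50 list calls and those of 29 of 496 gene results, most with CHD4 hairpins. Against shScramble it added only those of CHD4 in shFLI1 (log2 0.25) and mitochondrially encoded genes in shCHD4#1, both at 48 h. It also drops controls whose number no knockdown shares, so these changes need not reflect pairing. Lists that camera did not call were called in 24 cases with fry, 10 with no filter, 5 with kind as a term, and 11 and 3 in the second and first kinds alone. For shFLI1 numbers are not pairs (correlations -0.0927 to 0.0259 and -0.177 to -0.101). There the block gave 5561 and 5267 genes at 24 h and 6295 and 6412 at 48 h. It ended the 48 h ribosomal call (adjusted p = 0.0859).

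DESeq2 gave covariances with shFLI1 of 0.0937 for shCHD4#2 at 24 h and 0.211 and 0.347 for shCHD4#1 and shCHD4#2 at 48 h, and time differences of 3 and 669 genes. A filter at a mean of 50 gave 0.161 for the last covariance. For the time difference with shCHD4#1, 0 by limma, that filter, median centring, quantile normalisation and edgeR each gave 1. With an estimated correlation, camera called 0 lists in either direction with shFLI1 at 24 h and with both hairpins at both times, and 1 higher and 0 lower with shFLI1 at 48 h. Fry, a rotation test, called 2 higher and 3 lower with shCHD4#1 at 24 h, 9 higher with shFLI1, 3 higher with shCHD4#1 and 10 lower with shCHD4#2 at 48 h. Without a filter 2 lists were higher with shCHD4#1 at 48 h.

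With each library left out in turn, most low extremes came without replicate 2 of a CHD4 hairpin. At 24 h, counts with shCHD4#1 ranged from 424 to 1267 higher and 484 to 1584 lower, both lowest without its replicate 2, and 684 were higher without its replicate 3. With shCHD4#2 they ranged from 273 to 833 and 613 to 1488, lowest without its replicate 2, and 547 were higher without its replicate 3. Between hairpins the range was 874 to 1721, with 874 and 1285 without replicates 2 and 3 of shCHD4#1 and 991 without replicate 2 of shCHD4#2. Both hairpins called 156 to 361 higher and 141 to 339 lower, with 201 and 141 without replicate 2 of shCHD4#1, 156 and 143 without that of shCHD4#2, and 197 lower without shScramble replicate 3. At 48 h the ranges were 1684 to 2842 and 2015 to 3646 with shCHD4#1 and 2333 to 3909 higher with shCHD4#2, lowest without replicate 2 of each. Time differences ranged from 0 to 3 with shCHD4#1, with 3 without its 48 h replicate 1, 2 without its 24 h replicate 2 and 1 without 24 h shScramble replicate 5. With shCHD4#2 they ranged from 21 to 1404, at 1404, 21 and 85 without its 48 h replicates 1, 2 and 3, 56 without its 24 h replicate 1, 536 and 125 without 24 h shScramble replicates 2 and 3, and 146, 157 and 153 without 48 h shScramble replicates 3, 4 and 5. Lists lower with shFLI1 at 24 h were 2 to 4, with 4 without its replicate 1. Lists with shCHD4#1 at 24 h were 0 to 2 higher and 3 to 7 lower, at 0 higher without shScramble replicate 3 or 5 or its own replicate 3, 2 without shScramble replicate 1 or 2 or its own replicate 2, and 3 lower without its replicate 1. With shCHD4#2 at 24 h 0 to 2 were higher, 0 without its replicate 2 and 2 without its replicate 1, and with shCHD4#1 at 48 h 1 to 2, with 2 without shScramble replicate 2.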

Other observations

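The tests of parent genes and of opposite directions, and fits within 1 library kind, were chosen only after the result was seen. EWS-FLI1 and CHD4 knockdown were also set against each other, shFLI1 against the mean of both CHD4 hairpins. At 24 h 5893 genes were higher and 5224 lower with shFLI1, and at 48 h 6924 and 6894, or 10158 in all at 24 h and 14137 at 48 h among second-kind libraries alone. Cholesterol synthesis genes were higher with shFLI1 in 13 of 24 at 24 h and 16 at 48 h, against 1 lower at each time, with the same counts adjusted over the list alone (camera adjusted p = 0.00915 and 0.000454, and adjusted p = 0.9746 and 0.519 with an estimated correlation). Mitosis genes were higher with shFLI1 in 28 of 32 at 24 h (29 higher and 0 lower adjusted over the list alone; adjusted p = 2.25e-08, adjusted p = 0.629 with an estimated correlation) and lower in 24 at 48 h (1 higher and 24 lower adjusted over the list alone; adjusted p = 7.78e-05, adjusted p = 0.519 with an estimated correlation). Repressed targets were higher at 48 h in 25 of 29 (25 higher and 1 lower adjusted over the list alone; adjusted p = 2.53e-08, adjusted p = 0.0342 with an estimated correlation).

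The hairpins of CHD4 differed in 7963 genes at 48 h. Library kind as the cause is argued against by a correlation of 0.944 across genes between the hairpin difference in first-kind and in second-kind libraries. A different depth of CHD4 knockdown alone is argued against by 17.6 percent of genes called with both hairpins lying in opposite directions (505 of 2869, lower bound 16.2), where a deeper knockdown would give 1 direction. A larger loss of the EWS-FLI1 programme with shCHD4#2 is a candidate explanation that stays open, since the difference of shCHD4#2 minus shCHD4#1 correlated with the shFLI1 change at 0.108 across genes, between the bounds set in advance. The Spearman value, 0.0726, and the 24 h value, 0.0327, lay below them, while activated targets lay lower with shCHD4#2 in 21 of 42 and higher in 2. Off-target effects of 1 hairpin were not tested and cannot be excluded.

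With shFLI1 at 48 h, median fold change of 164 processed pseudogenes minus that of coding genes was -0.634 (95% bootstrap interval -0.745 to -0.502). Against second-kind controls it was -0.277 (-0.382 to -0.205), but pseudogene level defined the kinds and varied within them. Library kind stays open as the cause. Between kinds, pseudogenes were higher in the first by a median of 0.499, while 75 parent genes were at -0.356 (-0.396 to -0.318) and coding genes at -0.125. Whether reads moved between pseudogene and parent is open, as read numbers were not compared. A biological change was not tested.

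Fold changes correlated with GC content or gene length by at most 0.101 in size across the 97.8 percent of genes with annotation.

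Other splits of the same libraries were counted for each comparison. With shFLI1 9810 genes were called at 24 h (highest other split 4785) and 13429 at 48 h (7114), each 1 of 56 as large. Chance can be excluded only against splits that ignore library kind, and for the CHD4 hairpins only against splits that also ignore pairs. There 1 of 56 was as large for shCHD4#2 (2325, 1594 and 7964, 3343) and shCHD4#1 at 48 h (5965, 4481). With shCHD4#1 at 24 h it was 2 of 56 (2385), but the other, with 3668, followed library kind. The counts within the first kind were 865 and 867, while the second holds 1 library of that hairpin. The 8 splits that part all 3 pairs (highest other 0 in each comparison) are too few for a share under 0.05, and the other 48 part fewer pairs. Ignoring pairs and kinds, chance can be excluded for genes called with both hairpins (653, highest other 14, and 2364, 599), 1 of 100 each. So can it for shFLI1 against the hairpin mean (11117, 10588, and 13818, 11640), also 1 of 100. Between the hairpins (2022 and 7963 genes, highest other 0) the 10 splits are too few for a share under 0.05. For the number of called lists chance could not be excluded. At 24 h 33 of 56 splits gave at least the real 7 with shFLI1 (highest other 13), 18 the 7 with shCHD4#1 (10) and 23 the 7 with shCHD4#2 (13), and at 48 h 11 gave the 12 with shFLI1 (16), 16 the 9 with shCHD4#1 (12) and 15 the 8 with shCHD4#2 (13).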
